A study of Mus musculus with 6 samples.

How the data were processed

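RNA of primary mouse astrocytes was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, a 1-colour whole-transcript platform, with 1 array per sample and 3 arrays each for control and TNF (50 ng/mL, 24 h). The deposited table holds log2 values for 35544 probe sets on 6 arrays. The submitters' processing notes name RMA, which corrects background, normalizes quantiles between arrays and summarises probes, and limma; versions are not given in the sources used here. The base of the logarithm was read from the values, which ran from 2.04 to 14.37 with array medians from 7.14 to 7.18. RMA draws in large folds and leaves a floor under dim genes, and no detection calls were used here, so low values may lie near background. No value was missing and every column of the table was used.

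Probe sets were named through the platform annotation supplied with the table. Exactly 1 gene symbol was given for 21777 probe sets, several for 1621 and none for 12146, and only the first kind was used. Of these, 21686 matched a mouse RefSeq gene table (GRCm38.p6) by Entrez number, and 0 symbols needed updating. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over the 6 arrays was kept, which left 19926 genes. For 568 of those genes the probe set of highest variance was another one. No genome was used and no coordinates are given. List members without a probe set of their own, Gapdh among them, were not analysed here.

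Groups and replicate numbers came from the sample titles. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), TNF minus control, two-sided, without a block, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The residual degrees of freedom were 4, to which the prior added 3.70, and the median SE of a log2 difference was 0.14. Gene lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over 25 lists. An estimated correlation and fry, which tests a list without reference to other genes, stood beside it. With an estimated correlation camera takes its p from the residual degrees of freedom, 4 without and 2 with a block. This costs power, above all with the block. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the plots.

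The lists, 19 of pathways and 6 of other cell types that an astrocyte culture could hold, were written from general knowledge. The pathway lists were NF-kB pathway and feedback, chemokines, cytokines and growth factors, interferon-stimulated genes, MHC class I and antigen processing, complement and acute phase, mature astrocyte, neural progenitor and immaturity, Notch and BMP signalling, cell cycle, glycogen metabolism, glycolysis and lactate, cholesterol synthesis, extracellular matrix and proteases, prostaglandin and nitric oxide synthesis, oxidative stress response, and reactive astrocyte genes shared, A1 and A2. The cell type lists were microglia, oligodendrocyte and precursor, neuron, endothelial, fibroblast and mural, and ependymal markers. Some genes stand in more than 1 list. Named genes were the 10 with the largest positive and the 10 with the largest negative difference among those past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and a fixed set of astrocyte, progenitor, TNF receptor and reference genes (Gfap, Nes, Vim, Cd44, Msi1, Sox2, Pou5f1, Aqp4, Glul, Slc1a2, Slc1a3, Aldh1l1, Tnfrsf1a, Tnfrsf1b, Actb and, where measured, Gapdh). The groups, the test, the lists, the rule for named genes and most alternative settings were fixed before the data were examined.

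Control and TNF samples share the replicate numbers 1 to 3, and the numbers pair the samples by the values: the deviations from the group means correlated at 0.55, 0.65 and 0.75 for numbers 1, 2 and 3, against -0.53 to -0.04 between different numbers. Deviations cancel out within a group, so positive values for matched numbers force negative ones elsewhere. The negative range is therefore no separate evidence. The sample descriptions share a prefix within each number, whose meaning is not stated, so the pairing rests on the values. The consensus correlation within numbers was 0.65, and the fit with the number as a block, with 2 residual degrees of freedom, is given where it changed a call or moved a count by over 1.5 times. Replicate 3 also stood apart in its signals: the lower quartiles of its arrays were 6.27 and 6.33 against 6.01 to 6.09 in the others, and the upper quartiles 9.17 and 9.16 against 9.29 to 9.33.

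The alternatives were another centring, quantile normalization of the genes tested, filters on dim genes, other variance models, array weights, the replicate block, another probe set per gene, each array left out in turn, all probe sets, thresholds on size, a stricter adjusted p, and the other list tests. The scripts were tested on simulated data with 200 of 19926 genes changed, in 5 runs. Without simulated pairs the unblocked fit recovered 11.0%, 87.5% and 99.4% of genes changed by 0.5, 1 and 2 on the log2 scale, with 3.99% false among those called. With simulated pairs it recovered 4.48%, 84.2% and 97.9%, and the blocked fit recovered 73.4%, 99.4% and 100% with 6.47% false. The 200 changed genes are far fewer than the 1434 called in the data. The adjusted threshold depends on that number, so these rates may not hold for the data. A list of 25 genes shifted by 0.5 was called in 5 of 5 runs in each setting, and 0 of 100 unshifted lists were called. The simulated genes were drawn independently of each other, whereas the estimated correlation reached 0.76 in the cell cycle list and 0.81 in the microglia list. The 0 of 100 therefore does not measure false list calls among correlated genes.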

Results

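Gene expression was measured in primary astrocytes, the star-shaped support cells of the brain, grown in culture from mice of the C57BL/6J strain. Cultures received tumour necrosis factor (TNF), a pro-inflammatory cytokine, at 50 ng/mL and were collected after 24 h, beside control cultures collected at the same time. The 6 arrays comprised 3 control and 3 TNF samples, numbered 1 to 3 in each group. The comparison addresses whether an inflammatory signal moves astrocytes towards a progenitor-like state; NF-kB, a family of transcription factors activated by TNF, was not blocked in any sample. Values were log2 signals, and the differences given are TNF minus control. Array signals compress large folds, and the folds given tend to understate the ratios of transcripts. The number of arrays limits the precision, and the labels do not say that replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

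Interferon-response GTPases and chemokines showed the largest increases. Gbp4, a guanylate-binding GTPase of cell-autonomous immunity, rose from 5.23 ± 0.54 to 10.99 ± 1.10 (mean ± SD of log2 signal, n = 3 per group), a log2 difference of 5.76 with a standard error (SE) of 0.52, or 54.3-fold. Its relative Gbp5 rose 50.8-fold, with a log2 difference of 5.67 (SE 0.22). Ccl2, a chemokine that attracts monocytes, rose from 7.72 ± 0.91 to 13.23 ± 0.11, a 45.5-fold increase (limma adjusted p = 2.09e-04), and Ccl7 rose 35.3-fold. The other genes among the 10 largest increases were Phf11d, Ccl5, Ifi205, BC023105, Iigp1 and Irf7, with folds from 25.4 to 30.4.

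The largest decreases were smaller. Sstr2, a somatostatin receptor, fell by 2.81 on the log2 scale (SE 0.24, adjusted p = 4.75e-04), which was 7.03-fold lower. Rpe65, the retinoid isomerohydrolase, was 6.77-fold lower, Cmtm5 5.71-fold lower, and Gria2, an AMPA-type glutamate receptor subunit, 5.39-fold lower. Luzp2, Rgs2, St6galnac5, Abca8a, Slc39a12 and Prex2 completed the 10 largest decreases, between 4.05-fold and 5.27-fold lower. Without replicate 3 the calls of Gria2 (adjusted p = 0.0534) and Slc39a12 (adjusted p = 0.0508) were lost.

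**Figure D1:**
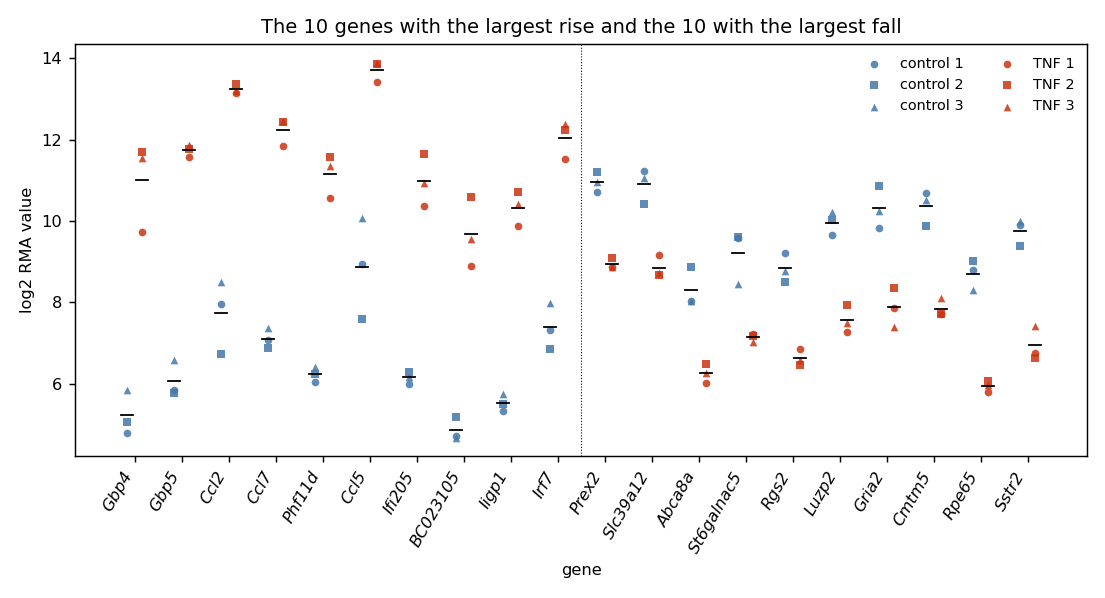
Log2 signal (vertical axis) of the 10 genes with the largest increases and the 10 with the largest decreases with TNF (horizontal axis). Each point is an array, its marker shape gives the replicate number, and each bar is a group mean. In all 20 genes the 3 TNF arrays lay on one side of the 3 control arrays.

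Of 19926 genes tested, 771 were higher and 663 lower with TNF at an adjusted p under 0.05 with limma. At an absolute log2 difference of at least 1 there were 365 higher and 200 lower, and at 4-fold or more 143 higher and 10 lower. In all 1434 called genes the groups did not overlap, which was true of 24.0% of all genes tested, against 10% by chance for 6 independent arrays. The samples pair by replicate number, so the share expected by chance is not exactly 10%. With the replicate number as a block, 1938 genes were higher and 2351 lower, and these included all 1434. The pairs are balanced, so the block leaves every log2 difference as it was and no sign can change. Without replicate 3, an alternative added after the data were seen, 401 were higher and 231 lower. Leaving out 1 array gave fewer calls in all 6 fits: 465 higher and 315 lower without control 1, 479 and 346 without TNF 2, 504 and 364 without control 3, 542 and 421 without control 2, 590 and 437 without TNF 1, and 669 and 455 without TNF 3.

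Genes of the NF-kB pathway and its feedback rose together. Of 19 measured members 16 rose and none fell, with a median log2 difference of 2.05; adjusted over the list alone, 17 rose. Tnfaip2, a TNF-induced protein, rose 15.5-fold with a log2 difference of 3.96 (SE 0.11, n = 3 per group, limma adjusted p = 6.29e-06). Nfkbie and Nfkbia, inhibitors that hold NF-kB in the cytoplasm, rose 19.7-fold and 10.2-fold, and Birc3, an inhibitor of apoptosis, rose 8.26-fold. The 3 members that did not pass were Tnip3 at 0.46, Tnfaip8 at 0.24 and Traf1 at -0.45; with the replicate block Tnip3 passed as higher (adjusted p = 0.0106) and Traf1 as lower (adjusted p = 0.0237). The list passed the camera test (adjusted p = 4.48e-30), also with an estimated correlation (adjusted p = 0.011). Of the TNF receptors, Tnfrsf1b rose from 7.48 ± 0.16 to 8.32 ± 0.22 (1.80-fold, adjusted p = 0.0142), while Tnfrsf1a differed by 0.20 (SE 0.13, adjusted p = 0.486). The call of Tnfrsf1b was lost without control 1 (adjusted p = 0.0608), without TNF 2 (adjusted p = 0.0541) and without replicate 3 (adjusted p = 0.103).

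Chemokines rose in 10 of 20 measured members with none lower, and in 15 adjusted over the list alone; 18 passed as higher with the replicate block. Besides Ccl2 and Ccl7, Cxcl10, which attracts activated T cells, rose 23.4-fold from 9.18 ± 1.11 to 13.73 ± 0.13 (n = 3 per group). Cxcl16 rose from 6.99 ± 0.43 to 10.98 ± 0.13 and Cx3cl1, the ligand of the microglial receptor Cx3cr1, rose 4.01-fold. Ccl11 at 0.05 and Ccl4 at 0.01 were the members nearest to no difference. The list's median log2 difference was 1.59 (camera adjusted p = 3.30e-18; adjusted p = 0.048 with an estimated correlation).

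Cytokines and growth factors rose in 6 of 22 members, over all genes and adjusted over the list alone, with none lower. Csf1, a growth factor of macrophages and microglia, rose 2.57-fold from 11.59 ± 0.10 to 12.95 ± 0.19 (n = 3 per group, limma adjusted p = 9.03e-04). Tnfsf13b, which supports B cells, rose 2.56-fold, and Il6 rose 3.41-fold from a low signal of 3.61 ± 0.19. Tnf itself differed by 0.30 and did not pass. The list passed camera (median 0.17, adjusted p = 1.47e-04) but not with an estimated correlation (adjusted p = 0.178) or without genes below the median signal (adjusted p = 0.0736). Without TNF 3 the median was 0.087 and without TNF 1 it was 0.27; 3 members rose without control 1, 3 without replicate 3, and 4 without control 2, control 3 or TNF 3.

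Interferon-stimulated genes rose in all 20 measured members, over all genes and adjusted over the list alone, with a median log2 difference of 2.97. Irf7, a transcription factor that amplifies interferon responses, rose 25.4-fold from 7.38 ± 0.56 to 12.05 ± 0.46 (n = 3 per group, limma adjusted p = 1.74e-04). Rsad2, the antiviral protein viperin, rose 17.9-fold, Gbp3 14.2-fold, Irf1 8.55-fold and Parp14 7.89-fold. The list passed camera (adjusted p = 2.46e-36), also with an estimated correlation (adjusted p = 0.046). The list means per array were 8.17, 8.05 and 8.42 in controls 1, 2 and 3 and 10.70, 11.36 and 11.17 in the TNF samples with the same numbers. Beside this list, the chemokines and the MHC class I genes, the microglia markers had a mean difference of 0.18 and were higher with TNF as a list in 3 of 3 pairs.

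MHC class I and antigen processing genes rose in 12 of 13 measured members, and in 13 adjusted over the list alone. The class I genes H2-K1, H2-D1, H2-T23, H2-Q6 and H2-Q7 had no probe set of their own and were not analysed here. The call of B2m was lost in 5 of the 6 fits without 1 array (highest adjusted p = 0.131, without control 1). The immunoproteasome subunits Psmb8, Psmb10 and Psmb9 rose 14.2-fold, 8.03-fold and 6.64-fold; Psmb8 went from 7.24 ± 0.14 to 11.06 ± 0.12 (n = 3 per group, limma adjusted p = 1.41e-05). Tapbp, which loads peptides onto MHC class I, rose 4.48-fold. Nlrc5, an activator of MHC class I transcription, differed by 0.53 (adjusted p = 0.145) and passed with the replicate block (adjusted p = 0.00282). Complement and acute phase genes rose in 10 of 17 measured members, and in 12 adjusted over the list alone. C3 had no probe set of its own and was not analysed here. Lcn2, the iron-siderophore binding protein lipocalin-2, rose 20.6-fold from 8.79 ± 0.40 to 13.15 ± 0.12. Ptx3, a soluble pattern recognition protein, rose 12.8-fold, and the complement proteases C1s1 and C1ra rose 7.18-fold and 3.74-fold. Both lists passed camera (medians 2.02 and 0.87, adjusted p = 3.06e-24 and 2.01e-13), each with adjusted p = 0.046 with an estimated correlation.

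Among mature astrocyte genes 9 of 29 members fell and none rose over all genes; adjusted over the list alone, 14 fell and 3 rose. Slc4a4, a bicarbonate cotransporter, fell by 1.31 on the log2 scale (SE 0.14, n = 3 per group, limma adjusted p = 0.00139), and Atp1b2, a sodium pump subunit, fell by 1.25. Glul, the glutamine synthetase that astrocytes use to clear glutamate, fell from 12.66 ± 0.11 to 11.78 ± 0.06 (1.85-fold lower, adjusted p = 0.00327), and Aldoc, aldolase C, was 2.01-fold lower. Gfap, the intermediate filament of astrocytes, was 11.91 ± 0.44 in controls and 11.40 ± 0.47 with TNF (log2 difference -0.51, SE 0.28, adjusted p = 0.42) and passed as lower with the replicate block (adjusted p = 0.00356). The water channel Aqp4 and the glutamate transporter Slc1a2 each differed by 0.60 (adjusted p = 0.0718 and 0.0617), and both passed as higher with the block (adjusted p = 0.0069 and 0.0123). Slc1a3 at -0.29 and Aldh1l1 at -0.08 did not pass in either fit.

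The mature astrocyte list had a median log2 difference of -0.49 and passed camera (adjusted p = 2.64e-07), but not with an estimated correlation (adjusted p = 0.0867). In the fit with the replicate block 16 members were lower and 3 higher. Without replicate 3, 4 were lower; without control 3 and without TNF 2 there were 5 and 6. Among the markers of other cell types, the 20 microglia markers had a median difference of 0.088 and the 14 fibroblast and mural markers one of -0.04. On all 6 arrays and without the block, Aqp4 and Slc1a2 were called higher without genes below the median signal (adjusted p = 0.0408 and 0.0343), with trend and robust variance (0.0334 and 0.0392) and with array weights (0.0485 and 0.0369). Aqp4 was also called without control 3 (adjusted p = 0.0428) and Slc1a2 without control 2 (adjusted p = 0.0294).

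Glycogen and glycolysis genes fell as lists. In glycogen metabolism 4 of 20 members fell and none rose, and 5 fell adjusted over the list alone. Ugp2, which makes the glucose donor for glycogen synthesis, fell by 1.39 on the log2 scale (SE 0.11, n = 3 per group, limma adjusted p = 3.08e-04). The others were Pygb, the brain glycogen phosphorylase, at -0.68, the glycogen-targeting phosphatase subunit Ppp1r3c at -1.34, and the phosphorylase kinase subunit Phkg1 at -1.41. In glycolysis and lactate metabolism 4 of 19 fell and none rose, and 7 fell adjusted over the list alone. Pfkp, a phosphofructokinase, fell by 1.37 (2.58-fold lower, adjusted p = 0.00337), Aldoc by 1.01, Pdk4, a pyruvate dehydrogenase kinase, by 0.99 and the glucose transporter Slc2a1 by 0.84. Both lists passed camera (medians -0.13 and -0.24, adjusted p = 8.47e-04 and 9.05e-05), also with an estimated correlation (adjusted p = 0.047 and 0.046).

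In the glycogen and glycolysis lists 7 members each were lower with the replicate block, and 1 glycolysis gene was higher. Without replicate 3, 1 glycogen and 3 glycolysis genes were lower; without control 1 there were 2 of each, and 2 and 1 glycogen genes without control 3 and without TNF 2. Single calls lost in some of the 6 fits without 1 array were those of Slc2a1 (5 fits, highest adjusted p = 0.111 without TNF 2), Phkg1 (3 fits, 0.0824 without control 1), Ppp1r3c and Pygb (2 fits each, 0.0574 without TNF 2) and Pdk4 (1 fit, 0.0581 without control 1).

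Neural progenitor and immaturity genes moved both ways. Of 30 measured members 3 rose and 4 fell; adjusted over the list alone 3 rose and 7 fell. Cd44, the hyaluronan receptor, rose 3.29-fold from 8.87 ± 0.29 to 10.59 ± 0.13 (n = 3 per group, limma adjusted p = 8.28e-04). Nes, the intermediate filament nestin of progenitor cells, fell by 0.97 on the log2 scale to 11.03 ± 0.16 (1.95-fold lower, SE 0.16, adjusted p = 0.0102). The other calls were Sox4 at 0.63 and Fut4 at 0.59 among the higher, and Notch1 at -0.54, its target Hes1 at -0.83 and the glial transcription factor Olig2 at -0.60 among the lower; Sox4, Fut4 and Olig2 were named after their values were seen. Msi1, an RNA-binding protein of progenitors, was 11.55 ± 0.25 and 11.00 ± 0.25 (log2 difference -0.55, adjusted p = 0.126) and passed as lower with the replicate block (adjusted p = 0.0117). Sox2 at -0.04 (SE 0.13, adjusted p = 0.967), Vim at -0.08 and Pou5f1, the pluripotency factor Oct4, at -0.06 (5.86 ± 0.30 and 5.80 ± 0.45) did not pass in either fit.

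The progenitor list did not pass camera (median -0.12, adjusted p = 0.0962), but passed as lower with fry (adjusted p = 0.00129), without genes below the median signal (0.0414) and with trend and robust variance (0.0436), and had adjusted p = 0.178 with an estimated correlation; with the replicate block 5 members were higher and 8 lower, and without replicate 3, 1 was higher and 1 lower. Each array left out reduced these counts: 1 higher and 2 lower without control 1 or TNF 2, 1 and 1 without control 2 or TNF 1, and 2 and 2 without control 3 or TNF 3. Notch1, Olig2, Sox4 and Fut4 each lost the call in 5 of the 6 fits (highest adjusted p = 0.0853, 0.0966, 0.13 and 0.164) and Hes1 in 4 (0.0901), and Nes lost it without replicate 3 (adjusted p = 0.0548).

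Notch and BMP signalling genes fell in 6 of 28 members and 1 rose; adjusted over the list alone 10 fell and 1 rose. Id4, an inhibitor of differentiation that responds to BMP signals, fell by 1.54 on the log2 scale (SE 0.15, n = 3 per group, limma adjusted p = 0.00106). The Notch target genes Hey1 and Hey2 were 2.53-fold and 2.23-fold lower. Bmp2, a ligand of the pathway, rose 5.39-fold from 5.55 ± 0.03 to 7.98 ± 0.56. The list passed camera (median -0.14, adjusted p = 6.51e-04), also with an estimated correlation (adjusted p = 0.046). The block gave 12 lower and 2 higher members; 3 were lower without control 1, and 4 without control 3 or TNF 2, and the median was -0.21 without TNF 3.

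Cell cycle genes lay below the controls as a list, but no single member of the 29 passed, over all genes or adjusted over the list alone. Ccna2, the S and G2 phase cyclin A2, was 9.19 ± 0.76 in controls and 7.91 ± 0.61 with TNF (n = 3 per group, log2 difference -1.28, SE 0.42, limma adjusted p = 0.13). Ccne2 differed by -1.17, Rrm2, a subunit of ribonucleotide reductase, by -1.13 and Pcna, the sliding clamp of replication, by -0.53. At an unadjusted p under 0.05 there were 9 lower and 0 higher members, and with the replicate block 17 were lower, Ccne2 with an adjusted p of 8.77e-04. The list passed camera (median -0.53, adjusted p = 2.57e-05), but not with an estimated correlation (adjusted p = 0.541) or with fry (adjusted p = 0.344). Replicate 2 was the highest in both groups: the list means were 8.23, 9.19 and 8.29 in controls 1 to 3 and 7.96, 8.37 and 7.70 in the TNF samples. The mean was lower with TNF in each pair. The median difference was -0.19 without control 2 (camera adjusted p = 0.0251), but that fit kept the high TNF 2 without its pair. Without replicate 3, 1 member was lower, and 8 with the block.

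Genes of reactive astrocytes were divided among lists named shared, A1 and A2 after published response types. In the shared list 8 of 13 members rose and none fell, and 9 rose adjusted over the list alone. These included Lcn2, Cxcl10 and Cd44, as well as Timp1, a metalloproteinase inhibitor, which rose 5.52-fold from 8.65 ± 0.28 to 11.11 ± 0.29 (n = 3 per group, limma adjusted p = 3.25e-04). In the A1 list 7 of 11 planned members were measured. Of these 7, 4 rose (Iigp1 27.9-fold, Psmb8, Serping1 at 0.97 and Srgn at 0.99) and the elastic fibre protein Fbln5 fell by 1.47. Adjusted over the list alone 5 rose and 1 fell. In the A2 list 3 of 13 rose (Ptx3, the transcription factor Stat3 at 0.58 and Cd14 at 0.71) and Cd109 fell by 1.25 and Emp1 fell by 1.84; adjusted over the list alone 4 rose and 2 fell. Srgn and Cd14 were named after their values were seen.

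The shared and A1 lists passed camera (medians 0.92 and 0.97, adjusted p = 1.48e-07 and 1.89e-04; both adjusted p = 0.046 with an estimated correlation), and the A2 list did not (median 0.084, adjusted p = 0.451; 0.028 with fry). In the blocked fit the shared list also had 2 lower members, and the A2 list had 5 higher and 3 lower. Without replicate 3 there were 5 higher in the shared list, 2 in A1 and 2 in A2, with 1 lower in A2. Higher A1 members numbered 2 without control 2 or TNF 3. Higher A2 members numbered 1 without control 1, TNF 1 or TNF 2, and lower ones 1 without control 1, TNF 2 or control 3. Serping1, Srgn, Stat3 and Cd14 each lost the call in 4 of the 6 fits without 1 array (highest adjusted p = 0.072, 0.0973, 0.0604 and 0.0806) and Emp1 in 3 (0.0587).

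Among extracellular matrix and protease genes 6 of 28 rose and 5 fell; adjusted over the list alone 11 rose and 8 fell. Mmp3, the protease stromelysin-1, rose 10.7-fold with a log2 difference of 3.42 (SE 0.52, n = 3 per group, limma adjusted p = 0.0077), and Adamts4, an aggrecanase, rose 1.94-fold. Lama2, a laminin chain, fell by 1.39 on the log2 scale (adjusted p = 0.0021). The other lower members, named after their values were seen, were Sparcl1 at -0.89, Bcan at -0.80, Fn1 at -0.87 and Ncan at -1.31; Bcan and Ncan encode lectican proteoglycans of the brain matrix. The list as a whole did not pass camera (median 0.094, adjusted p = 0.479). The replicate block gave 11 higher and 8 lower, and leaving out replicate 3 gave 2 and 2. There were 3 higher without control 1 or TNF 2, 4 without TNF 1 or control 3, and 2 lower without TNF 1, control 2 or control 3 and 3 without TNF 3; Fn1 and Ncan lost the call in 4 fits (highest adjusted p = 0.0835 and 0.126), Bcan in 3 (0.0764) and Sparcl1 in 1 (0.0608). Mmp3 and Adamts4 lost the call without replicate 3 (adjusted p = 0.105 and 0.101).

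In prostaglandin and nitric oxide synthesis 3 of 14 members rose and none fell, and 6 rose adjusted over the list alone. Ptges, the inducible prostaglandin E synthase, rose 6.06-fold from 7.60 ± 0.08 to 10.20 ± 0.20 (n = 3 per group, limma adjusted p = 4.78e-05). Gch1, which makes the cofactor of nitric oxide synthases, rose 2.68-fold and Nos2, the inducible nitric oxide synthase, 2.48-fold, while Ptgs2 differed by 0.29 and did not pass. The list passed camera (median 0.22, adjusted p = 4.03e-04; adjusted p = 0.046 with an estimated correlation), and 7 members were higher with the replicate block. The call of Nos2 was lost without control 1 (adjusted p = 0.0611).

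Of 16 oxidative stress response genes 3 fell and 1 rose, over all genes and adjusted over the list alone. Gclm, a subunit of the enzyme that starts glutathione synthesis, fell by 0.74 on the log2 scale (SE 0.12, n = 3 per group, limma adjusted p = 0.0114), the metallothionein Mt1 by 0.70 and catalase, Cat, by 0.46. Slc7a11, the cystine and glutamate exchanger, rose 2.38-fold (adjusted p = 0.0403). The list passed camera (median -0.16, adjusted p = 0.00348) but not with an estimated correlation (adjusted p = 0.147) or without TNF 3 (adjusted p = 0.0563). With the block 6 were lower; without replicate 3, 1 was lower and 0 higher, and 1 was lower without control 1 or TNF 1. Gclm lost the call without replicate 3 (adjusted p = 0.0854). Cat lost the call in all 6 fits without 1 array (highest adjusted p = 0.178) and with the probe set of highest variance per gene (adjusted p = 0.052), Slc7a11 in 4 (0.134) and Mt1 in 3 (0.0647), and Slc7a11 also after quantile normalization (adjusted p = 0.0568). With the replicate block on all arrays, Cat, Slc7a11 and Mt1 passed (limma adjusted p = 0.00504, 0.00195 and 0.00314).

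No cholesterol synthesis gene of 19 passed over all genes or adjusted over the list alone with limma (4 higher and 0 lower at an unadjusted p under 0.05). Dhcr7, the last enzyme of the pathway, differed by 0.52 (SE 0.15, n = 3 per group, adjusted p = 0.0973), and Fdps by 0.51, Mvd by 0.37 and Mvk by 0.35. With the replicate block 5 were higher, Dhcr7 with an adjusted p of 0.00617, and Dhcr7 also passed without control 2 (adjusted p = 0.0387) and with array weights (0.0441). The list did not pass camera (median 0.03, adjusted p = 0.257), but passed with array weights (median 0.24, adjusted p = 0.0313), without control 2 (0.18, adjusted p = 0.00648) and without TNF 3 (0.17, adjusted p = 0.0456).

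**Figure D2:**
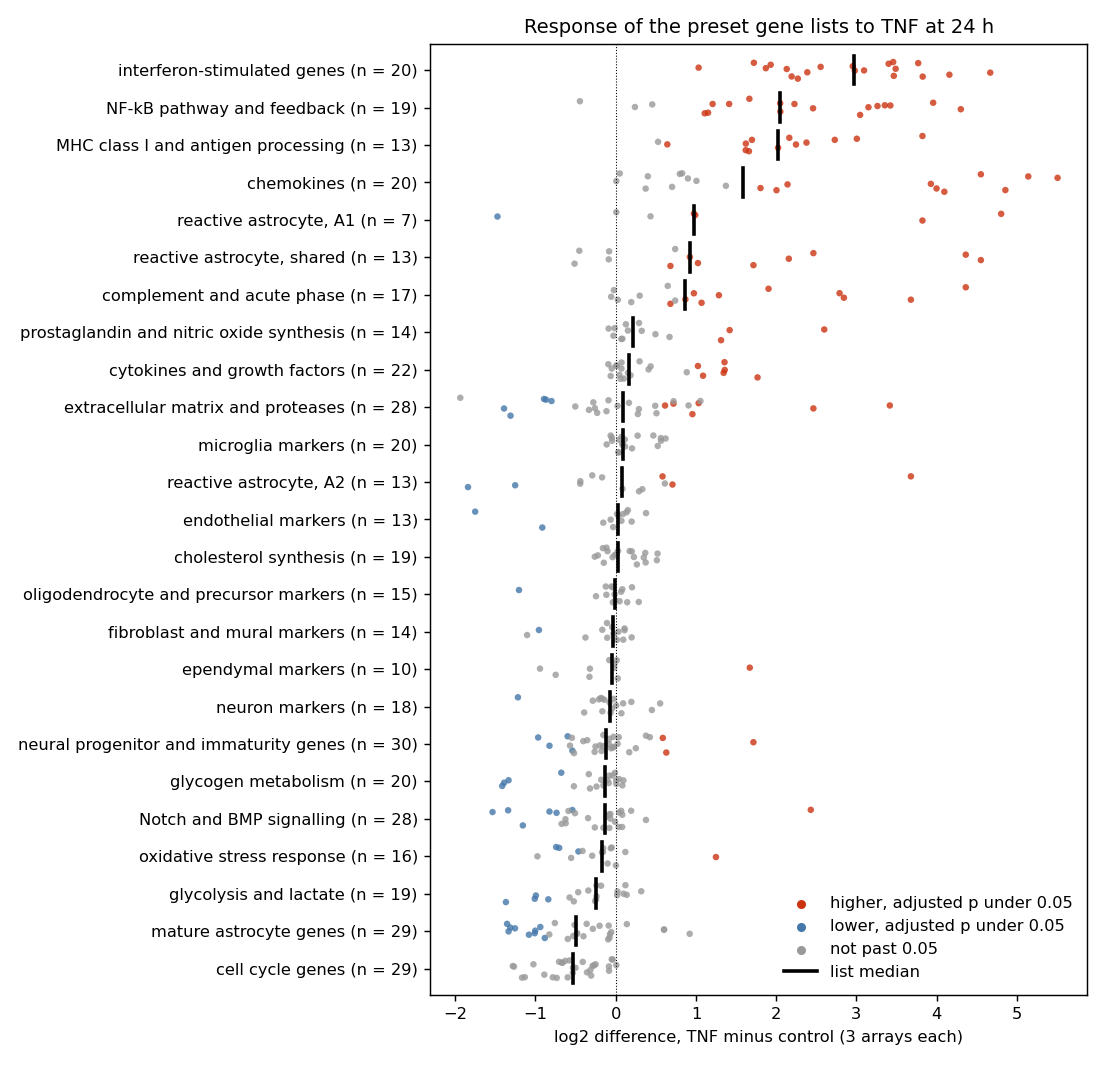
Log2 difference, TNF minus control, of the measured members of the 25 gene lists. Each point is a gene, red where higher, blue where lower and grey where not past an adjusted p of 0.05, and each black bar is a list's median. The medians ran from -0.53 for cell cycle genes to 2.97 for interferon-stimulated genes.

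Markers of other cell types passed in few members. None of 20 microglia markers passed over all genes or adjusted over the list alone (1 higher and 0 lower at an unadjusted p under 0.05); the lysosomal protein Cd68 differed by 0.57 (adjusted p = 0.216) and C1qb was 7.86 ± 1.53 in controls and 8.42 ± 1.40 with TNF (n = 3 per group). With the replicate block 4 microglia markers were higher: Itgb2 (adjusted p = 0.00335), Itgam (0.0137), C1qb (0.0205) and Cd68 (0.0307), of which Itgam (0.0885) and C1qb (0.364) did not pass with the number as a random effect, and the list passed camera (median 0.088, adjusted p = 0.383 without and 0.0346 with the block), though not with the block and an estimated correlation (adjusted p = 0.349). It also passed unblocked without TNF 2 (median 0.57, adjusted p = 0.0031) and without control 3 (0.50, adjusted p = 0.00485). Each of these fits left 1 array without its pair, and the list varied by replicate number. Its means were 6.30 and 6.41 in control and TNF of replicate 2, and 7.55 and 7.67 in replicate 3. Leaving out the low TNF 2 or the high control 3 thus raised the difference by itself. Olig1, an oligodendrocyte lineage factor, fell by 1.21 on the log2 scale (limma adjusted p = 0.00786), as 1 of 15 oligodendrocyte markers. Map2, a microtubule-associated protein of neurons, fell by 1.22, as 1 of 18 neuron markers. The anion transporter Slco1a4 fell by 1.75 and the VEGF receptor Kdr by 0.91, as 2 of 13 endothelial markers. Acta2, smooth muscle actin, fell by 0.96 as 1 of 14 fibroblast and mural markers, with Tagln at -1.10 (adjusted p = 0.0649, and 0.00293 with the block), and Rarres2, which encodes the chemoattractant chemerin, rose 3.18-fold as 1 of 10 ependymal markers.

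Adjusted over the list alone the oligodendrocyte, neuron, endothelial and ependymal counts were the same, and 2 fibroblast and mural markers fell. With the replicate block 1 neuron marker was higher and 3 lower, 1 endothelial marker was higher, 3 fibroblast and mural markers were lower and 3 ependymal markers were lower. These 5 lists did not pass camera, with medians of -0.01, -0.07, 0.03, -0.04 and -0.05 in the order oligodendrocyte, neuron, endothelial, fibroblast and mural, and ependymal (adjusted p = 0.627, 0.31, 0.612, 0.383 and 0.515); the endothelial mean was -0.14, opposite in sign to its median. Acta2 lost the call without control 1, control 2 or control 3 (highest adjusted p = 0.0632), and Tagln gained one without TNF 1 (adjusted p = 0.0435), without genes below the median signal (0.0436) and with trend and robust variance (0.0392). The ependymal marker Dnah11, a dynein chain, differed by -0.75 (adjusted p = 0.103) and was called lower with the block (0.00183), without control 2 (0.0273) and with array weights (0.0475). The fibroblast and mural list passed without TNF 3 (median -0.21, adjusted p = 0.0456). Without replicate 3 no oligodendrocyte, fibroblast and mural, or ependymal marker passed, with adjusted p = 0.067 for Olig1, 0.0939 for Acta2 and 0.054 for Rarres2. Actb, the cytoskeletal actin used as a reference gene, differed by -0.04 (SE 0.10, adjusted p = 0.932).

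The arrays separated by treatment first and by replicate number second. The first principal component carried 57.5% of the variance and parted the TNF from the control arrays. The second carried 23.6% and set both replicate 3 arrays (24.8 and 29.2) apart from the other 4 (-21.3 to -3.35). Microglia markers varied with the replicate number: their list means were 6.90 and 7.23 in control and TNF of replicate 1, 6.30 and 6.41 in replicate 2, and 7.55 and 7.67 in replicate 3. The mature astrocyte list means were 10.34, 10.23 and 10.37 in controls 1 to 3 and 9.85, 9.75 and 9.92 in the TNF samples, lower in 3 of 3 pairs. With the replicate block and an estimated correlation together, no list passed camera (lowest adjusted p = 0.201). That setting has 2 residual degrees of freedom and hardly any power: interferon-stimulated genes, all 20 higher, had an adjusted p of 0.207. The calls lost there do not speak against any list.

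**Figure D3:**
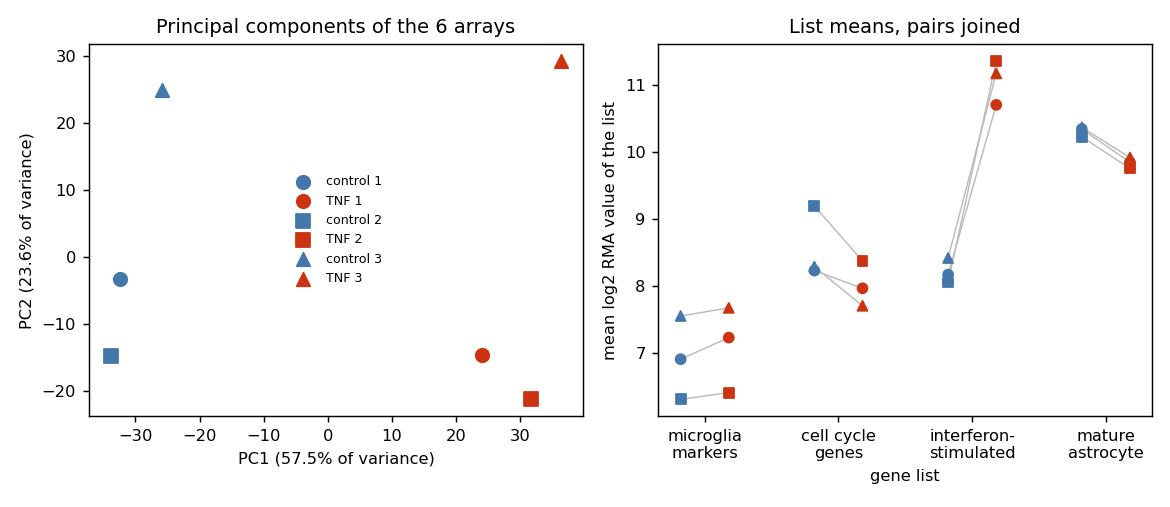
Left, the 6 arrays on the first and second principal components of the log2 signals, where both replicate 3 arrays have the highest values of the second component (24.8 and 29.2). Right, the mean log2 signal per array of 4 gene lists, with control and TNF of the same replicate number joined by a line.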

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

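Leaving out both arrays of a replicate number, and the replicate block with a log2 difference of at least 1, were chosen only after the results were seen; the other alternatives were planned. Against 771 genes higher and 663 lower, the counts were 1938 and 2351 with the replicate block, 2231 and 2471 with the number as a random effect, 365 and 200 at an absolute log2 difference of at least 1, 378 and 258 with both block and that size, 415 and 234 with the treat test, 386 and 195 at an adjusted p under 0.01, 1154 and 973 with array weights, and 436 lower over all probe sets. Leaving out 1 array gave 465 to 669 higher and 315 to 455 lower, the lowest without control 1 and the highest without TNF 3. Without replicate 3 they were 401 and 231, and with the block 1801 and 2258 without replicate 1, 1275 and 1660 without replicate 2, and 1250 and 1451 without replicate 3. Median centring, quantile normalization, dim-gene filters, trend with robust variance and the probe set of highest variance kept both counts within 1.5 times; 1390 of the 1434 calls were shared after quantile normalization, 603 without replicate 3 and 1397 with the other probe set, none with the opposite sign.

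Camera called 9 lists higher and 6 lower, and 8 and 3 with an estimated correlation. That setting ended the calls of cytokines (median 0.17), mature astrocyte (-0.49), cell cycle (-0.53) and oxidative stress genes (-0.16), with adjusted p = 0.178, 0.0867, 0.541 and 0.147. Fry ended the cell cycle call (-0.53, adjusted p = 0.344) and called A2 (0.084, 0.028) and progenitor genes (-0.12, 0.00129), neither of them with the block (0.18 and 0.0514). Progenitor genes were also called with the median filter (-0.17, 0.0414) and trend with robust variance (-0.12, 0.0436), with adjusted p = 0.178 at an estimated correlation, cholesterol genes with array weights (0.24, 0.0313), and microglia markers with the replicate block (0.088, 0.0346), also with the block and without replicate 2 (0.14, 0.00653) or replicate 3 (0.14, 0.00597). Cytokines lost the call with the median filter (0.44, 0.0736). Single arrays left out gave medians of -0.0049 to 0.18 for cholesterol genes, called without control 2 or TNF 3, -0.12 to 0.57 for microglia markers, called without TNF 2 (0.57) or control 3 (0.50), -0.21 to 0.11 for fibroblast and mural markers, called without TNF 3, -0.19 to -0.18 for oxidative stress genes, lost without TNF 3, and -0.71 to -0.19 for cell cycle genes. Without the block, the cholesterol, microglia, and fibroblast and mural lists each had adjusted p = 0.845 at an estimated correlation on all 6 arrays. The replicate block with an estimated correlation ended all list calls (lowest adjusted p = 0.201), but with 2 residual degrees of freedom it had hardly any power. Over the other alternatives 504 of 524 list results and 2216 of 2426 named-gene results were on the same side of the threshold, and none reversed. Settings that change only the variance or the test leave the differences as they were and cannot reverse a gene. Besides the named genes whose blocked p stands in the report, the replicate block called Rrm2 (adjusted p = 0.002), Pla2g4a (0.00259), Ccna2 (0.00463), Fdps (0.00943), Mvd (0.0171), Mvk (0.0181), Pcna (0.0195), Dynlrb2 (0.014), Abcb1a (0.014), Pdgfrb (0.0146) and Stmn2 (0.0398); it changed no other call of a named gene or list. Fewer samples or genes account for part of the lower counts. Leaving out 1 array without the block also breaks a pair, so differences between replicate numbers enter the treatment difference. List and single-gene calls gained or lost in those fits may reflect this. The blocked fits without replicate 1, 2 or 3 ended no unblocked call of a named gene made on all 6 arrays. Otherwise the cause was not tested. Dim genes may lie near background, which limits what any of these settings can show, as for the cytokine median of 0.44 once they were filtered.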

Other observations

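The families in the next 2 paragraphs were chosen by symbol after the values were seen, as were both tests on replicate 3 and the one without Acta2 and Tagln; the other tests were planned. Guanylate-binding and immunity-related GTPases rose in 9 of 10 members (median log2 difference 3.86), among them Gbp9 at 3.95 and Gbp7 at 2.73. MHC class II genes rose in 3 of 9: Cd74, the invariant chain, from 5.86 ± 0.18 to 10.40 ± 0.32 (4.54, SE 0.18, n = 3 per group, limma adjusted p = 2.03e-05), H2-Aa at 3.43 and H2-Ab1 at 2.43; 6 were higher with the replicate block. Genes of inflammasomes, pyroptosis and necroptosis rose in 7 of 13: Casp4, the caspase that senses intracellular lipopolysaccharide, at 4.64 (SE 0.12, adjusted p = 6.29e-06), Mlkl, the executor of necroptosis, at 3.70, and Zbp1, a nucleic acid sensor, at 3.50, while Nlrp3 at 0.29 and Aim2 at 0.07 did not pass. Of 10 Toll-like receptors Tlr2 rose by 4.01 and Tlr3 by 0.95, the latter not without control 1 (adjusted p = 0.0622); 1 receptor was higher without replicate 3. The first 3 families passed camera (adjusted p = 6.95e-21, 1.23e-05 and 2.11e-10, over 11 families), but each had adjusted p = 0.121 with an estimated correlation, and the Toll-like receptors did not pass (0.0685). The families here and in the next paragraph were chosen after their values were seen, so their camera p-values are descriptive only. The preset correlation of 0.01 may also make those p-values too small. Estimated correlations of the planned lists ran from -0.054 (A1) to 0.81 (microglia markers). The estimated correlation leaves 4 residual degrees of freedom, so the calls lost with it may reflect low power. Correlation among the members is equally open, since some planned lists passed at the same degrees of freedom.

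Some neurotransmitter receptor genes fell. Of 23 glutamate receptor genes 4 fell: Gria2 by 2.43, Gria1 by 1.59 (SE 0.17, n = 3 per group, limma adjusted p = 0.00141), Grin2b by 1.09 and Grik3 by 0.59, and 10 were lower with the replicate block. Of 16 GABA-A receptor subunits Gabrb1 fell by 1.63, Gabra4 by 1.25 and Gabrg1 by 0.73, and 5 were lower with the block. Of 13 smooth muscle type contractile genes 5 fell (median -0.83), namely Myl9 at -1.35, Cnn1 at -1.09, Acta2 at -0.96, Lmod1 at -0.92 and Cnn2 at -0.83, and 8 with the block. Of 87 potassium channel genes 7 fell and 1 rose, with Kcnj13 at -1.93, Kcnk2 at -1.47 and Kcnf1 at 1.99; 15 were lower and 3 higher with the block. The lower potassium channels numbered 2 without control 3, 3 without TNF 1 or TNF 2, and 4 without control 1 or control 2, and the higher ones 2 without TNF 3. Of the 14 constitutive proteasome core subunits 2 rose, Psma6 at 0.72 and Psma5 at 0.58, and 7 with the block. Axonemal genes (0 of 19) and cytosolic ribosomal protein genes (0 of 58) had no call with limma, against 6 lower axonemal and 5 higher ribosomal genes at an unadjusted p under 0.05, and 9 lower and 7 higher with the block. Camera passed these families (adjusted p = 1.51e-04 glutamate, 0.00173 GABA, 1.51e-06 contractile, 0.0376 potassium, 1.23e-05 proteasome, 0.00492 axonemal, 1.12e-04 ribosomal), none with an estimated correlation (adjusted p = 0.132, 0.132, 0.267, 0.601, 0.279, 0.43 and 0.461). Calls lost in some of the 6 fits without 1 array were those of Kcnd3 (6 fits, highest adjusted p = 0.122 without control 3), Kcnc2, Kcnh5 and Kcnmb1 (5 fits each, 0.0909 without TNF 2, and 0.116 and 0.121 without TNF 1), Kcnj10 (2 fits, 0.0701 without control 1), Grik3 and Psma5 (5 fits each, highest adjusted p = 0.16 and 0.117, both without TNF 2), Psma6 (3 fits, 0.0609 without TNF 2), Acta2 and Cnn2 (3 fits each, 0.0632 and 0.0859 without control 2) and Grin2b (2 fits, 0.0801 without TNF 1). Lower glutamate receptors numbered 2 without TNF 2, lower contractile genes 3 without control 2 or control 3, and higher proteasome subunits 0 without control 2, TNF 2 or control 3 and 1 without control 1 or TNF 1; 3 axonemal genes were lower without control 2. Without replicate 3 the lower calls numbered 1 glutamate receptor, 3 potassium channels and 2 contractile genes, and 0 potassium channels and 0 proteasome subunits were higher.

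A hypothesis was that mature astrocyte genes fell because the TNF cultures held a smaller share of astrocytes, which would raise the markers of every other cell type alike. For a scale shift left by normalization, the list's median was -0.47 after a further quantile normalization. RMA had already normalized quantiles, and the upper quartiles were alike in the groups (9.17 to 9.29 in controls, 9.16 to 9.33 with TNF). The further step could therefore hardly move the median, and it decides little. A smaller share of astrocytes cannot be told apart from an unchanged one. The 5 bright fibroblast and mural markers had a mean log2 difference of -0.45 (95% bootstrap interval -0.90 to -0.007), which met the bound set in advance. However, the interval resampled 5 markers, not arrays. The means were 0.34 (0.19 to 0.50) for bright microglia, -0.44 (-1.21 to 0.14) for oligodendrocyte, -0.34 (-0.99 to 0.32) for neuron and 0.11 (-0.70 to 1.17) for ependymal markers. Without Acta2 and Tagln, of the contractile family above, the mean of the other 3 fibroblast and mural markers was -0.069 (-0.38 to 0.20). Both were left out after their falls were seen, so that mean had to rise and decides nothing. A smaller share alone would lower mature astrocyte genes alike, but 16 were lower and 3 higher with the replicate block. A change in the astrocytes themselves after TNF also stays open and may differ between genes, as Slc25a18 was at 0.92 (adjusted p = 0.0589, and 5.60e-04 with the replicate block).

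Interferon-stimulated, chemokine and MHC class I genes could have risen with a larger share of microglia. The 6 bright microglia markers (Cd68, Tyrobp, Fcer1g, C1qb, C1qc and Laptm5) had a median difference of 0.36 (95% bootstrap interval 0.10 to 0.56). This was below the 1 that the explanation needed, though not wholly below the bound of 0.5 set in advance, so a smaller contribution stays open. The interval resampled markers, not arrays, and does not measure the spread between arrays, where C1qb alone had an SE of 0.87. Interferon gene transcription in the cultures at 24 h cannot be told apart from its absence: 0 of 11 measured Ifna, Ifnb1 and Ifng genes were higher at an adjusted or an unadjusted p under 0.05, but only Ifna5 was brighter than the median gene (7.63). Its upper limit of 0.49 met the bound of 0.5 set in advance, but 1 gene is too few to exclude it, and earlier transcription was not sampled. A response of the astrocytes to TNF itself stays open as the design's own explanation.

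Replicate 3 differed from replicates 1 and 2 in 2619 genes with treatment in the fit. That fit took the arrays as independent, although those of the same number correlated at 0.65. The contrast is 1 replicate against 2, and replicate 3 was chosen after it stood apart. Its gene counts are therefore descriptive only, and no like count was made for replicate 1 or 2. A different intensity distribution of the replicate 3 arrays is a candidate explanation for part of the 2619 genes, since 592 remained after quantile normalization. Another share of other cell types is a further one. Bright microglia markers were higher by 1.48 in replicate 3 (95% bootstrap interval 0.98 to 1.86), and by 1.58 (1.10 to 1.94) after quantile normalization. Fibroblast and mural markers were higher by 0.38 (0.25 to 0.47). The intervals resampled markers, not arrays. Replicates 1 and 2 were pooled, although the microglia list means were 6.90 and 7.23 in replicate 1 and 6.30 and 6.41 in replicate 2. In replicate 3 they were 7.55 and 7.67. The low replicate 2 adds to the 1.48, so the microglia signal does not set replicate 3 alone apart. Both explanations stay open. The design names no difference between the replicates, so no explanation taken from the design was tested.

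For the counts of genes higher and lower with TNF, 3 against 3 arrays make 10 splits, so the share of splits with as many calls cannot go under 0.1. The real split, 1 of 10, called 771 higher and 663 lower, and the highest other split called 0. The 3 other splits that also parted all pairs called 0 genes with the replicate block, against 4289. Every other split mixes TNF and control arrays within its groups, so the treatment difference adds to the residual spread. Their 0 calls therefore do not estimate how many genes chance would call.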
